A study of Arabidopsis thaliana with 9 samples.

How the data were processed

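Leaves of 9 week old Arabidopsis thaliana, accession Shahdara, were sampled from 3 groups: the wild type, a line labelled as an IAA26 knockout and a line labelled as IAA26 stable. Each group had 3 libraries that the labels call biological replicates. Per the labels' protocols, RNA was extracted with an RNeasy plant kit and libraries were made with a NEB Next Ultra kit. Whether the counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

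The authors deposited 1 table with a set of columns per library. Per the file headers, it holds counts of total exon reads, unique exon reads, total gene reads, intron reads and exon-exon reads for each gene, which are whole numbers and were not normalized. The authors also deposited RPKM values, which were found equal to total exon reads per kilobase of exon length divided by 1 constant per library, of 30.6 M to 47.9 M reads. Other columns that the authors deposited, per the file headers, are exon length, chromosome, start and end, and an expression value that equalled the RPKM in all 9 libraries. The headers name reads as paired and trimmed before mapping. The genome build is TAIR10 per the submitters' processing notes. The aligner, the counter, the annotation version and their settings are not given in the sources used here. Column names were matched to samples through the sample titles, and 0 columns of per-sample values were left unmatched. Of 32833 gene identifiers, 32536 were found in the reference annotation used here, 32520 of them with the same start and end. Positions are as the table gives them, and the exon structure of IAA26 is from the reference annotation of the same build.

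Total exon reads served as counts. They summed to 28585976 to 45346301 per library, of which 96.7% to 97.4% were unique. In total 8383 genes had no read in any library, and 581 genes with at least 100 reads drew over 50% of their reads from shared positions; named genes with few unique reads are marked in the text. A gene was tested if it passed edgeR's filterByExpr with a minimum count of 10, a minimum total of 15 and a minimum share of 0.7, which left 19409 genes. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. All 9 libraries entered 1 fit with a mean per group and no covariate, so that the groups shared 6 residual degrees of freedom (prior degrees of freedom 2.36, biological coefficient of variation 0.247). Calls were made at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Single values per library were compared with exact two-sided permutation tests, which cannot give a p under 0.1 with 3 against 3. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

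Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 on log2 CPM (prior count 2), adjusted over 20 lists per comparison, and beside it with a correlation estimated per list and with fry. The lists were Aux/IAA repressors, auxin-induced, transport and perception genes, salicylic acid defence, pattern-triggered immunity and camalexin, jasmonate and ethylene defence, leaf senescence, vegetative phase change and flowering, nuclear photosynthesis genes, the circadian clock, abscisic acid with drought and cold, heat shock, flavonoids and anthocyanins, glucosinolates, RNA silencing with tobamovirus host factors, cell expansion, dividing cells, and markers of phloem, xylem, trichomes with the stomatal lineage, and flower, meristem and seed. They hold 355 members, of which 354 were in the table and 326 were tested; AOP2 was the member not found there. Tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule each comparison names IAA26, the 6 largest rises and 6 largest falls among called genes whose groups do not overlap and whose mean is at least 1 RPKM, and up to 4 called members of each list with the smallest p. Where a list had no called member, the 1 with the smallest p is given by its values. One gene the rule picked in the third comparison is not reported here, while counts over the rule and the lists still include it. Outside the rule, and after their values were seen, CYP79F2, IAA12, WRKY53, CCA1, RVE8, TOC1, BOA, PRR7, PRR9, CBF2, COR15A, KIN1, KIN2, RD20, BIK1 and PEN3 were named to spell out counts, and AP3 and AG for their levels in 1 library.

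The gene tests, the list tests and the overlap were checked on simulated data with known answers. The permutation, binomial and Fisher tests and the splits of libraries were not. Counts for 19409 genes were drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. EdgeR recovered 44% and 83% of these in knockout-labelled against wild type, 41% and 79% in stabilised against wild type, and 38% and 76% in stabilised against knockout-labelled, with 5, 7 and 7 calls among unchanged genes. Of the changed genes it tested in the same data, DESeq2 recovered 67.0% and 89.9%, 60% and 91%, and 66.3% and 86.9%. It made 66, 74 and 45 calls among unchanged genes, and limma on RPKM made 8, 6 and 5. Counts were drawn gene by gene with edgeR's estimates of spread, so these calls do not give the false share of DESeq2's real calls. At these rates of recovery many 2-fold changes would be missed with these libraries. For the overlap of both lines' responses, unchanged groups and the controls they share were simulated 20 times. In the simulation of single genes the remaining glucosinolate genes were moved 2-fold as well. Camera with either correlation and fry called that list in each comparison. Among the unchanged lists, camera with a preset correlation called 0, 1 and 0.

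Alternatives were DESeq2 1.42.0, RLE factors, library totals alone, no filter and a stricter filter of at least 10 reads in 6 libraries, limma on log2(RPKM + 0.5) and with pseudocounts of 0.1 and 1 (at least 1 RPKM in 3 libraries). Others were limma after quantile normalization, fits of only the 2 groups compared, the replicate number as a block, organelle genes left out, thresholds of 0.01 and 0.1, a test against a fold of 1.5, and each library left out in turn. Added after seeing the data were unique exon reads, total gene reads, a term for the libraries numbered 2, and a fit without those libraries. EdgeR was set as the test for whole read counts before the data were examined. DESeq2, run on the same counts, and limma on RPKM are therefore given as alternatives. Raw reads were not analysed here.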

Results

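RNA was sequenced from leaves of 9 week old Arabidopsis thaliana of the natural accession Shahdara. The 9 libraries formed 3 groups of 3, which the labels call biological replicates. The groups were the wild type, a line labelled as an IAA26 knockout and a line labelled as IAA26 stable, called stabilised below. IAA26 is a member of the Aux/IAA family of repressors, which hold back auxin-responsive transcription until auxin triggers their degradation. According to the series' design text, the lines served a search for genes of leaf development and defence. Exon reads per library numbered 34325905, 45346301 and 37631865 in the wild type, 33066761, 36547078 and 35257124 in the knockout-labelled line and 28585976, 32235117 and 36684424 in the stabilised line. Of 32833 genes listed, 24450 had a read and 19409 were expressed enough to be tested. Fold changes below are log2 values with their standard error (SE). Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named, and levels are RPKM as mean ± SD of 3 libraries.

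IAA26 (AT3G16500) lies on the minus strand of chromosome 3 from 5612203 to 5614803 in TAIR10. The reference annotation gives it 2 transcripts, of 4 and 5 exons, with coding regions that start at 5612886 and 5612801 and both end at 5614208. Its level was 17.5, 18.5 and 20.3 RPKM in the wild-type libraries (18.7 ± 1.44, n = 3), 16.7, 17.2 and 12.4 RPKM in the knockout-labelled libraries (15.5 ± 2.64, n = 3) and 12.7, 9.81 and 10.3 RPKM in the stabilised libraries (10.9 ± 1.51, n = 3). These values rest on 1337 to 1841, 978 to 1387 and 698 to 849 exon reads per library. By these RPKM means the knockout-labelled line held 82.5% and the stabilised line 58.4% of the wild-type transcript level. After TMM scaling edgeR's fit gave 0.760-fold and 0.615-fold. Its quasi-likelihood test did not call the difference of the knockout-labelled line (log2 fold change -0.40, SE 0.11, Benjamini-Hochberg adjusted p = 0.12). DESeq2 put the same fold of -0.40 past the threshold (adjusted p = 0.0342). On simulated data of this comparison it made 66 calls among unchanged genes where edgeR made 5, and recovered 67.0% of 2-fold changes where edgeR recovered 44%. Those data were drawn with edgeR's estimates of spread, so they do not give the false share of DESeq2's real calls. Over all alternatives, edgeR, limma and DESeq2 gave the comparison adjusted p values from 0.0342 to 1.00. In the stabilised line IAA26 fell (log2 fold change -0.70, SE 0.12, adjusted p = 0.0112). The direct comparison of the 2 lines gave -0.31 (SE 0.12, adjusted p = 0.122). A transcript can persist where a lesion removes only the protein, and the position of the lesion is not given in the sources used here. The transcript level alone therefore does not check the label, and the line is called knockout-labelled throughout.

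On the first principal component of log2 CPM, which held 44.3% of the variance, stabilised 2 and 3 scored 87.8 and 71.5 while stabilised 1 scored -3.01, among the wild-type scores of -34.0 to -0.456. Knockout-labelled 1 and 2 scored -56.7 and -51.5, and knockout-labelled 3 scored -4.58. Correlations of log2 expression across genes were 0.951 to 0.988 within groups and 0.915 to 0.975 between groups, where genes are not independent replicates. The floral organ genes AP3 and PI were high in knockout-labelled 3 alone: AP3 reached 4.46 RPKM against 0.112 to 0.323 in the other 8 libraries, and PI 8.44 RPKM against 0.336 to 0.952. SEP3 was highest in that library too but reached 5.62 RPKM in stabilised 1, and AG stood there at 2.51 RPKM against 1.03 to 2.08 in the others. List means of log2 CPM, centred over the 9 libraries, set stabilised 1 apart from stabilised 2 and 3 as well. They were -0.50 against 0.70 and 0.64 for nuclear photosynthesis genes, 1.19 against -2.41 and -2.14 for flavonoid synthesis, and -1.23 against 1.34 and 1.67 for cell expansion. Chloroplast-encoded genes took 0.339% ± 0.0137 of exon reads in the wild type, 0.274% ± 0.0226 in the knockout-labelled and 0.280% ± 0.0378 in the stabilised libraries. Each line differed from the wild type with p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 3 allows. Across all 3 groups the libraries numbered 2 had fewer intron reads, at 3.79% to 4.03% of gene reads against 4.61% to 4.99% in the others.

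**Figure D1:**
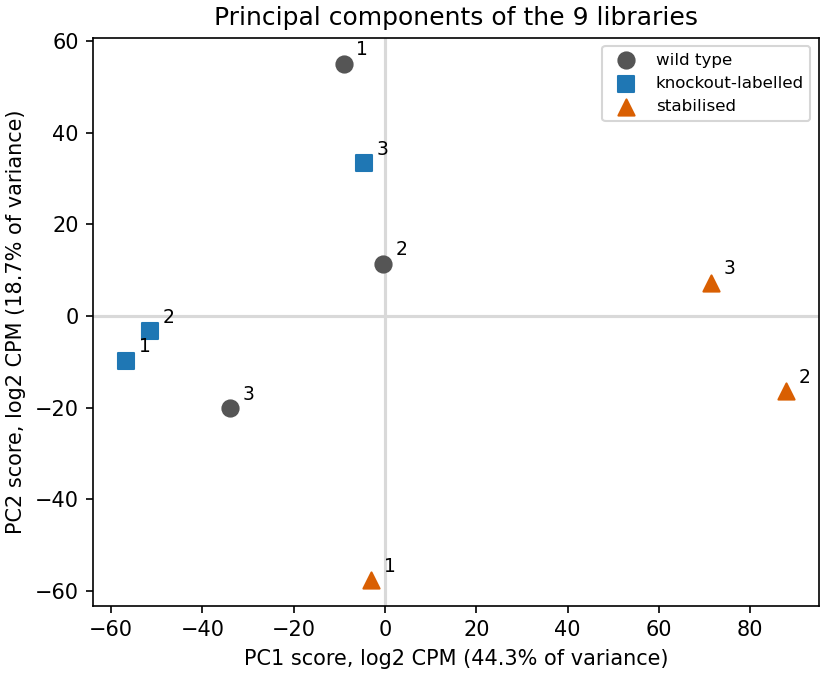
Scores of the 9 libraries on the first 2 principal components of log2 CPM, 1 point per library with its replicate number and group. The first component (44.3% of the variance) sets stabilised 2 and 3 apart at 87.8 and 71.5, while stabilised 1 lies at -3.01.

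The first comparison asked which leaf transcripts differ when the line is labelled as lacking IAA26. In knockout-labelled leaves several clock and cold genes were higher and several glucosinolate genes lower than in the wild type. CBF3 (AT4G25480, listed as DREB1A; chromosome 4, 13018010 to 13019400), a transcription factor of cold acclimation, rose 15.4-fold from 0.303 ± 0.0801 to 5.10 ± 0.384 RPKM (n = 3 each, log2 3.94, SE 0.20, adjusted p = 0.000541). PRR5 (AT5G24470, listed as APRR5; chromosome 5, 8356204 to 8358546), a clock repressor, rose from 0.468 ± 0.0414 to 3.44 ± 0.606 RPKM (log2 2.76, SE 0.17, adjusted p = 0.000836). The largest fall among genes with a mean of at least 1 RPKM was that of BHLH100 (AT2G41240; chromosome 2, 17198037 to 17199454), a transcription factor of the iron deficiency response, from 9.73 ± 7.70 to 0.236 ± 0.221 RPKM (log2 -5.44, SE 1.05, adjusted p = 0.0475). In total 322 genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05, of which 180 were higher and 142 lower, and 63 and 55 of these changed at least 2-fold. An unadjusted p under 0.05 was reached by 3809 genes. The 3 knockout-labelled and 3 wild-type values did not overlap for 5693 genes, or 29.3%, where chance gives 10%.

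Other large rises were those of DJC76, a chloroplast DnaJ-domain protein (log2 2.99, adjusted p = 0.0113), CBF1 (2.74, adjusted p = 0.0336), AT1G56300, another DnaJ-domain gene (2.62, adjusted p = 0.00261), and ADO3, the blue-light receptor FKF1 (2.43, adjusted p = 0.0035). Falls were led, after BHLH100, by its relative ORG2 (bHLH38; log2 -4.57, adjusted p = 0.0423) and by PAD3 (listed as CYP71B15; -4.39, adjusted p = 0.0454), the last enzyme of camalexin synthesis. AT1G68238 (-3.19, adjusted p = 0.0224), the glycosyltransferase UGT74E1 (-2.94, adjusted p = 0.0164) and the glutaredoxin GRXS10 (-2.83, adjusted p = 0.0319) followed. PAD3 varied widely in the wild type, at 48.5 RPKM in wild type 1 and 5.95 and 8.23 RPKM in wild type 2 and 3, against 0.847 to 1.24 RPKM in the knockout-labelled libraries.

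Among 14 circadian clock genes, PRR5, ELF3 and PRR3 rose and LHY fell, with 7 higher and 2 lower when adjusted over the list alone. LHY (AT1G01060; chromosome 1, 33365 to 37871), a dawn-phased repressor, fell from 112 ± 28.3 to 30.8 ± 6.92 RPKM (log2 -1.99, adjusted p = 0.0175). ELF3, part of the evening complex, rose by 1.04 on the log2 scale (adjusted p = 0.0164), and PRR3 went from 1.36 ± 0.237 to 3.64 ± 0.713 RPKM (adjusted p = 0.0206). Camera with a preset correlation left the clock list short of the threshold (adjusted p = 0.0508, and adjusted p = 0.451 with an estimated correlation). The list holds dawn genes and later genes, which a test of 1 direction sets against each other. Fry called it, with adjusted p = 0.0207 for 1 direction and adjusted p = 3.28e-07 for mixed directions. Of 18 genes of abscisic acid, drought and cold, 3 rose: CBF3, CBF1 and the cold-protective COR15B (log2 1.97, adjusted p = 0.0405). Adjusted over the list alone, 5 were higher and 2 lower, and camera placed the list higher (adjusted p = 0.00123, and adjusted p = 0.377 with an estimated correlation). The median of 0.46 was 0.77 without wild type 1.

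**Figure D2:**
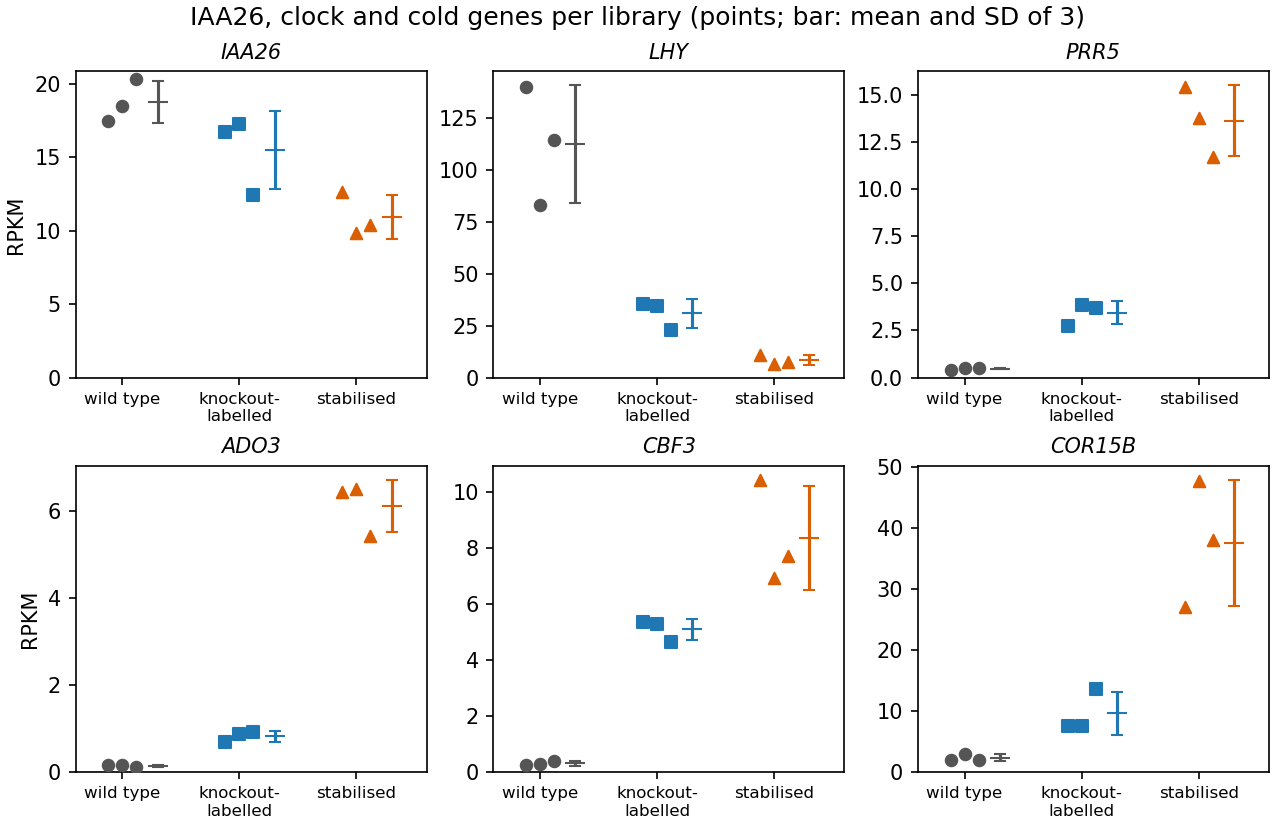
RPKM of IAA26 and of 5 clock and cold genes in each library (points), with the mean and SD of 3 libraries per group (bars). PRR5 goes from 0.468 RPKM in the wild type through 3.44 in the knockout-labelled to 13.6 in the stabilised line, and LHY from 112 through 30.8 to 8.24.

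Glucosinolate metabolism, the source of sulphur-containing defence compounds, had 5 of 20 genes lower in knockout-labelled leaves, 10 when adjusted over the list alone, and all 20 log2 fold changes were below 0 (median -0.79). The list mean was -0.61 and -0.82 in knockout-labelled 1 and 2 but -0.15 in knockout-labelled 3. It was 0.25, 0.34 and -0.19 in wild type 1, 2 and 3, so knockout-labelled 3 did not lie below wild type 3. SOT17, a sulfotransferase of the last step of the core pathway, fell from 60.7 ± 5.91 to 33.8 ± 4.86 RPKM (log2 -0.95, adjusted p = 0.0257). SOT18 (-0.85, adjusted p = 0.0201), SUR1 (-0.85, adjusted p = 0.0292), FMO-GSOX1 (-1.17, adjusted p = 0.0455) and CYP79F2 (-0.54, adjusted p = 0.0458) fell too. Camera gave the list an adjusted p = 3.03e-08, and adjusted p = 0.377 with an estimated correlation. In the jasmonate and ethylene list edgeR called 0 of 26 genes, with 18 lower at an unadjusted p under 0.05 and 14 lower by DESeq2. The median there was -1.60, 24 members were below 0, 16 were lower when adjusted over the list alone, and camera gave an adjusted p = 9.06e-09 (adjusted p = 0.451 with an estimated correlation). JAZ9, a repressor of jasmonate signalling, stood at 280 ± 79.0 RPKM in the wild type and 84.4 ± 15.5 in the knockout-labelled line (log2 -1.83, adjusted p = 0.0717). For pattern-triggered immunity and camalexin, PAD3 was the 1 of 21 genes that fell, with 7 lower when adjusted over the list alone, and the median was -0.36, and -0.18 without wild type 2 (camera adjusted p = 0.00819, and adjusted p = 0.451 with an estimated correlation).

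Nuclear photosynthesis genes had a median of -0.24, with 26 of 27 below 0, though the mean of the list was lower in knockout-labelled 1 and 2 (-0.53 and -0.45) and not in knockout-labelled 3 (0.08, against -0.17 to 0.13 in the wild type). The median was -0.11 and -0.13 without knockout-labelled 1 or 2 and -0.44 without knockout-labelled 3, and it was -0.13 with library totals alone. EdgeR called 0 of them, over all genes and adjusted over the list alone, 5 were lower at an unadjusted p under 0.05 and DESeq2 called 3 lower. Camera placed the list lower (adjusted p = 0.00649, and adjusted p = 0.826 with an estimated correlation), and GAPB, of the Calvin cycle, gave -0.52 (adjusted p = 0.142). Trichome and stomatal lineage markers had a median of 0.68. EdgeR called 0 of 5 over all genes and 3 higher when adjusted over the list alone, 4 were higher at an unadjusted p under 0.05, and DESeq2 called 2. Camera placed them higher (adjusted p = 0.00168, and adjusted p = 0.377 with an estimated correlation), with the guard cell factor MYB60 at 0.57 (adjusted p = 0.0894). Markers of flower, meristem and seed had a median of 1.96 over 4 genes, of which edgeR called 0 over all genes and 2 higher when adjusted over the list alone. There 2 were higher at an unadjusted p under 0.05, DESeq2 called 1, and camera gave an adjusted p = 0.126 (adjusted p = 0.733 with an estimated correlation). PI, at log2 2.69 (adjusted p = 0.165), owed its mean to 8.44 RPKM in knockout-labelled 3.

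In the Aux/IAA family 1 of 22 genes fell, IAA17 (log2 -0.51, adjusted p = 0.0319), also when adjusted over the list alone, around a median of 0.04 and a mean of -0.01 (camera adjusted p = 0.974, and adjusted p = 0.987 with an estimated correlation). Of 21 auxin-induced, transport and perception genes edgeR called 0, over all genes and adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05 and 1 higher by DESeq2. Their median was 0.07 and their mean -0.17 (camera adjusted p = 0.772, and adjusted p = 0.980 with an estimated correlation), and the auxin-conjugating GH3.5 gave 0.55 (adjusted p = 0.129). Salicylic acid defence had a median of -0.01, which turned positive with scaling by library totals alone, and edgeR called 0 of 26 genes on either adjustment, with 3 lower unadjusted and 2 lower by DESeq2 (camera adjusted p = 0.444, and adjusted p = 0.980 with an estimated correlation). GRX480, a glutaredoxin induced by salicylic acid, gave -1.66 (adjusted p = 0.117). Leaf senescence had a median of -0.25 and 0 calls among 22 genes on either adjustment in edgeR, against 6 lower unadjusted and 1 lower by DESeq2 (camera adjusted p = 0.151, and adjusted p = 0.810 with an estimated correlation). Its member WRKY45 gave -0.85 (adjusted p = 0.112). Of 19 genes of vegetative phase change and flowering, the floral repressor MAF5 fell from 8.29 ± 2.02 to 1.70 ± 0.378 RPKM (log2 -2.40, adjusted p = 0.0175). Adjusted over the list alone 1 was higher and 1 lower, with a median of 0.18 and a mean of -0.06 (camera adjusted p = 0.663, and adjusted p = 0.826 with an estimated correlation).

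EdgeR called 0 members over all genes in 6 further lists of this comparison. Heat shock had a median of -0.48 over 9 genes, 0 past the list-alone adjustment, 1 higher and 1 lower unadjusted and 1 lower by DESeq2 (camera adjusted p = 0.374, and adjusted p = 0.849 with an estimated correlation). The median was 0.07 without wild type 1 and -0.75 without wild type 2. The member HSP17.6A gave -1.79 (adjusted p = 0.12). Flavonoid and anthocyanin synthesis had a median of 0.69 over 15 genes, 0 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.779, and adjusted p = 0.987 with an estimated correlation). The median was -0.59 without knockout-labelled 2, and 0.17, 0.22 and 2.64 without wild type 1, 2 or 3. Chalcone isomerase CHI gave -0.57 (adjusted p = 0.421). RNA silencing and tobamovirus host factors had a median of 0.09 over 18 genes, 1 higher and 1 lower when adjusted over the list alone, 4 higher and 1 lower unadjusted, and 1 and 1 by DESeq2 (camera adjusted p = 0.210, and adjusted p = 0.810 with an estimated correlation). TOM1, a host factor of tobamovirus replication, gave -0.52 (adjusted p = 0.0563). Cell expansion had a median of 0.14 over 12 genes while camera pointed down (adjusted p = 0.974, and adjusted p = 0.987 with an estimated correlation). EdgeR put 0 past the list-alone adjustment and 1 lower unadjusted, DESeq2 called 0, and the expansin EXPA4 gave -0.60 (adjusted p = 0.181). The median was 0.47, 0.28 and -0.58 without knockout-labelled 1, 2 or 3, and 0.62 and -0.18 without wild type 1 or 3. Phloem markers had a median of -0.14 over 10 genes, 1 lower when adjusted over the list alone, 2 lower unadjusted and 1 by DESeq2 (camera adjusted p = 0.349, and adjusted p = 0.634 with an estimated correlation). Among them the sucrose exporter SWEET11 gave -0.77 (adjusted p = 0.0543). Xylem markers had a median of -0.46 over 6 genes with 0 past the list-alone adjustment, 0 unadjusted and 0 by DESeq2 (camera adjusted p = 0.374, and adjusted p = 0.849 with an estimated correlation), and XCP2 gave -0.84 (adjusted p = 0.577). Of 11 genes of dividing cells, 1 rose, the growth regulator GRF1 (log2 1.22, adjusted p = 0.0209), also when adjusted over the list alone (median 0.08, camera adjusted p = 0.894, and adjusted p = 0.987 with an estimated correlation).

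The count of 322 genes rested on few libraries: it was 11 and 10 without knockout-labelled 1 or 2, 144 without knockout-labelled 3, 116, 94 and 30 without wild type 1, 2 or 3, 108 without stabilised 3 and 546 without stabilised 1. Of the 23 calls picked by the naming rule 4 (CBF3, PRR5, AT1G56300 and ADO3) held in all 9 such fits. With the replicate number as a block edgeR called 134 genes, and 12 of the 23 calls were kept. Scaling by library totals alone put the median log2 fold change of all genes at 0.12, against 0.00323 with TMM, and gave 204 higher and 94 lower. Limma on RPKM gave 251 and 118, and DESeq2 called 784 higher and 994 lower. Medians of further lists, not called by camera, moved by over 1.5 times without 1 library. Their ranges, with the library left out at each end, were: Aux/IAA genes -0.04 (wild type 3) to 0.07 (wild type 2), auxin-induced, transport and perception genes -0.14 (knockout-labelled 3) to 0.13 (wild type 1) and salicylic acid defence -0.22 (wild type 1) to 0.11 (wild type 3). Other ranges were: the clock 0.22 (wild type 1) to 0.53 (wild type 2), dividing cells -0.33 (knockout-labelled 3) to 0.42 (knockout-labelled 1) and senescence -0.40 (knockout-labelled 2) to -0.19 (wild type 3). Other ranges were: RNA silencing 0.07 (knockout-labelled 1) to 0.15 (knockout-labelled 3), phloem -0.23 (wild type 3) to 0.03 (knockout-labelled 1) and xylem -1.40 (knockout-labelled 3) to -0.10 (knockout-labelled 1). Other ranges were: flower, meristem and seed 0.51 (knockout-labelled 3) to 3.14 (knockout-labelled 1).

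The second comparison asked which leaf transcripts differ in the line labelled as IAA26 stable. Here ADO3, PRR5, CBF3 and LHY stood further from the wild type than in knockout-labelled leaves, 6 of 21 genes of pattern-triggered immunity were higher, and 3 of 9 heat shock genes were lower. Camera called both of these lists with a preset correlation but not with an estimated one (adjusted p = 0.638 and 0.734). ADO3 (AT1G68050; chromosome 1, 25508639 to 25510907) rose 45.8-fold from 0.140 ± 0.0246 to 6.12 ± 0.596 RPKM (n = 3 each, log2 5.52, SE 0.21, adjusted p = 1.89e-05). PRR5 rose 30.5-fold to 13.6 ± 1.87 RPKM (log2 4.93, SE 0.18, adjusted p = 1.89e-05) and CBF3 28.6-fold to 8.35 ± 1.85 RPKM (log2 4.84, SE 0.21, adjusted p = 3.05e-05). LHY fell to 8.24 ± 2.40 RPKM (log2 -3.71, SE 0.26, adjusted p = 0.000472). EdgeR's quasi-likelihood test called 1721 genes, 987 higher and 734 lower, of which 473 and 222 changed at least 2-fold, and 5253 genes had an unadjusted p under 0.05. Groups did not overlap for 5494 genes, or 28.3%, where chance gives 10%.

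The other large rises were those of AT4G37240 (log2 5.78, adjusted p = 0.0302), the touch-induced cell wall enzyme TCH4 (listed as XTH22; 5.42, adjusted p = 0.0178) and AT4G30650, a gene of low-temperature-responsive membrane proteins (4.66, adjusted p = 0.0014). TCH4 stood at 10.8, 176 and 109 RPKM in stabilised 1, 2 and 3, against 2.53 ± 0.922 in the wild type. Large falls were those of CAD8 (-4.66, adjusted p = 0.033), the small heat shock protein HSP17.6A (-3.36, adjusted p = 0.0129) and the glutathione transferase GSTU24 (-3.18, adjusted p = 0.00835). KCS2 (-3.41, adjusted p = 0.0303) and UGT73B4 (-3.25, adjusted p = 0.0289) fell as well, but only 54.2% and 14.5% of their reads were unique, so their values may include reads of near copies.

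Of 14 clock genes 8 rose and 3 fell, and 9 and 4 when adjusted over the list alone (median 1.16, camera adjusted p = 0.0303, and adjusted p = 0.638 with an estimated correlation). Besides PRR5 and LHY, PRR3 rose by 2.30 (adjusted p = 0.000712) and ELF3 by 1.43 (adjusted p = 0.000797). The dawn genes CCA1 (-1.64, adjusted p = 0.0108) and RVE8 (-1.85, adjusted p = 0.00419) fell with LHY. In the abscisic acid, drought and cold list 8 of 18 rose and 1 fell, and 12 and 1 when adjusted over the list alone (median 1.14, camera adjusted p = 1.44e-05, and adjusted p = 0.154 with an estimated correlation). COR15B rose from 2.27 ± 0.577 to 37.6 ± 10.4 RPKM (log2 4.15, adjusted p = 0.00113), RD29A by 2.89 (adjusted p = 0.00152) and CBF1 by 4.44 (adjusted p = 0.00217). CBF2, COR15A, KIN1 and KIN2 rose too, while the drought-induced caleosin RD20 fell by 1.37 (adjusted p = 0.0174). Heat shock genes had a median of -1.64: 3 of 9 fell, 7 when adjusted over the list alone (camera adjusted p = 0.00353, and adjusted p = 0.734 with an estimated correlation). HSP90.1 fell by 1.93 (adjusted p = 0.0318) and HSP101 by 1.66 (adjusted p = 0.0418).

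In pattern-triggered immunity and camalexin 6 of 21 genes rose, and 11 were higher and 3 lower when adjusted over the list alone (median 0.71, and 0.46 without stabilised 2, camera adjusted p = 0.00353, and adjusted p = 0.638 with an estimated correlation). The transcription factor WRKY33 went from 53.0 ± 22.1 to 181 ± 97.1 RPKM (log2 1.82, adjusted p = 0.0263). The kinase gene MPK3 rose by 0.98 (adjusted p = 0.0101), the myrosinase PEN2 by 0.71 (adjusted p = 0.0115) and the co-receptor BAK1 by 0.52 (adjusted p = 0.0395). BIK1 and PEN3 were the other 2 that rose. Of 26 salicylic acid genes SAG101 (log2 0.73, adjusted p = 0.0136) and SARD1 (1.35, adjusted p = 0.0499) rose, 1 when adjusted over the list alone (median 0.42, and 0.26 without wild type 1, camera adjusted p = 0.0134, and adjusted p = 0.811 with an estimated correlation). Of 26 jasmonate and ethylene genes the lipoxygenase LOX4 rose (log2 1.99, adjusted p = 0.0433). EdgeR called 0 when adjusted over the list alone, with 5 higher and 4 lower unadjusted and 2 and 2 by DESeq2 (median 0.67, and 0.07 without stabilised 2, camera adjusted p = 0.185, and adjusted p = 0.811 with an estimated correlation). Glucosinolate metabolism had a median of 0.24 and 0 calls among 20 genes on either adjustment in edgeR, with 3 higher unadjusted and 2 by DESeq2 (camera adjusted p = 0.214, and adjusted p = 0.811 with an estimated correlation). MYB51 gave 1.44 (adjusted p = 0.0635). Flavonoid synthesis had all 15 members below 0 (median -0.77), of which CHI fell (-1.47, adjusted p = 0.0427), the 1 call also when adjusted over the list alone (camera adjusted p = 0.0238, and adjusted p = 0.811 with an estimated correlation). The mean of the list in stabilised 1 (1.19) lay among those of wild type 1, 2 and 3 (-0.53, -0.46 and 1.81), and stabilised 2 and 3 lay below them. The median was -3.47 and -0.51 without stabilised 1 or 2, and -1.26, -1.22 and -0.13 without wild type 1, 2 or 3.

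In the Aux/IAA family 3 of 22 rose and 2 fell, and 5 and 3 when adjusted over the list alone (median 0.27, camera adjusted p = 0.513, and adjusted p = 0.811 with an estimated correlation). IAA29 rose by 3.19 (adjusted p = 0.0414), IAA3 by 1.09 (adjusted p = 0.039, 84.5% of its reads unique) and IAA9 by 0.49 (adjusted p = 0.0254), while IAA17 fell by 0.49 (adjusted p = 0.0127) and IAA12 by 0.69 (adjusted p = 0.0427). Of 21 auxin-induced, transport and perception genes GH3.5 rose (log2 0.68, adjusted p = 0.0407) and the auxin receptor gene AFB3 fell (-0.62, adjusted p = 0.00616, 72.2% unique). It was 1 and 1 when adjusted over the list alone (median 0.40, camera adjusted p = 0.519, and adjusted p = 0.811 with an estimated correlation). In the senescence list 3 of 22 fell, and 3 were higher and 3 lower when adjusted over the list alone (median -0.14, camera adjusted p = 0.384, and adjusted p = 0.811 with an estimated correlation). NAP, a transcription factor that promotes leaf senescence, fell from 90.8 ± 5.52 to 30.8 ± 13.0 RPKM (log2 -1.51, adjusted p = 0.0093), NAC092 by 1.03 (adjusted p = 0.0379) and WRKY45 by 1.03 (adjusted p = 0.0356). Of 19 phase change and flowering genes the flowering activator SOC1 rose (0.81, adjusted p = 0.0448) and the repressor SNZ fell (-0.68, adjusted p = 0.0376). It was 1 and 1 when adjusted over the list alone as well (median -0.27, camera adjusted p = 0.552, and adjusted p = 0.811 with an estimated correlation).

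Photosynthesis genes had a median of 0.44, carried by stabilised 2 and 3, since the list mean of stabilised 1 (-0.50) lay below the wild type, yet the 1 of 27 called, RCA, the activase of Rubisco, fell (-0.69, adjusted p = 0.0498). EdgeR called 0 when adjusted over the list alone, with 1 higher and 1 lower unadjusted and 1 and 1 by DESeq2 (camera adjusted p = 0.381, and adjusted p = 0.811 with an estimated correlation). Of 12 cell expansion genes TCH4 and XTH9 (1.74, adjusted p = 0.0337) rose and EXPA4 fell (-0.99, adjusted p = 0.0316). It was 2 and 1 when adjusted over the list alone as well (median 1.02, camera adjusted p = 0.384, and adjusted p = 0.811 with an estimated correlation). GRF1 was the 1 of 11 genes of dividing cells that rose (0.97, adjusted p = 0.0142), also when adjusted over the list alone (median 0.33, camera adjusted p = 0.492, and adjusted p = 0.811 with an estimated correlation). SGS3, a component of RNA silencing, was the 1 of 18 in its list that rose (0.52, adjusted p = 0.00801), also when adjusted over the list alone (median -0.04, camera adjusted p = 0.519, and adjusted p = 0.811 with an estimated correlation). Of 10 phloem markers SWEET11 (-1.09, adjusted p = 0.00695) and PP2-A1 (-0.49, adjusted p = 0.0274) fell. Adjusted over the list alone 2 fell as well, around a median of 0.01, which turned negative with library totals alone, and a mean of -0.03 (camera adjusted p = 0.384, and adjusted p = 0.811 with an estimated correlation). EdgeR called 0 members on either adjustment in 3 marker lists. Xylem had a median of 0.46 over 6 genes, with 0 unadjusted and 0 by DESeq2 (camera adjusted p = 0.885, and adjusted p = 0.947 with an estimated correlation) and ATHB8 at -0.26 (adjusted p = 0.28). Trichome and stomatal markers had a median of -0.19 over 5 genes, with 1 lower unadjusted and 0 by DESeq2 (camera adjusted p = 0.384, and adjusted p = 0.811 with an estimated correlation) and GL2 at -0.56 (adjusted p = 0.149). Flower, meristem and seed markers had a median of 0.78 over 4 genes, with 0 unadjusted and 0 by DESeq2 (camera adjusted p = 0.636, and adjusted p = 0.811 with an estimated correlation) and SEP3 at 0.85 (adjusted p = 0.416).

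The count of 1721 genes became 3786 without stabilised 1, 584 and 848 without stabilised 2 or 3, 744 and 736 without wild type 1 or 3 and 1002 and 1021 without knockout-labelled 1 or 2, whose libraries enter the shared estimate of spread. Of the 45 calls picked by the naming rule 19 held in all 9 such fits, DESeq2 called 3418 genes, and limma on quantile-normalized RPKM gave 893 higher and 1087 lower. Medians of further lists, not called by camera, moved by over 1.5 times without 1 library. Their ranges, with the library left out at each end, were: Aux/IAA genes 0.21 (stabilised 3) to 0.43 (wild type 2), auxin-induced, transport and perception genes 0.08 (stabilised 3) to 0.56 (stabilised 1) and senescence -0.61 (stabilised 1) to -0.02 (stabilised 3). Other ranges were: phase change and flowering -0.27 (knockout-labelled 1) to -0.04 (stabilised 3), photosynthesis 0.23 (stabilised 2) to 0.72 (stabilised 1) and glucosinolate metabolism 0.00628 (stabilised 2) to 0.39 (stabilised 1). Other ranges were: cell expansion 0.45 (wild type 3) to 1.43 (stabilised 1), dividing cells -0.12 (stabilised 3) to 0.72 (stabilised 1) and RNA silencing -0.14 (stabilised 1) to -0.00479 (stabilised 2). Other ranges were: phloem -0.09 (stabilised 3) to 0.07 (stabilised 1), xylem 0.12 (stabilised 3) to 0.84 (stabilised 1) and trichome and stomatal markers -0.30 (stabilised 2) to -0.13 (wild type 1).

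The stabilised line was also compared directly with the knockout-labelled line, and with a preset correlation the smallest camera p values there were those of the jasmonate, glucosinolate and immune lists, each higher in stabilised leaves. With an estimated correlation these lists were not called (adjusted p = 0.478, 0.285 and 0.285). The smallest p values were then those of the immune list (unadjusted p = 0.0177) and of abscisic acid, drought and cold (unadjusted p = 0.0419). JAZ7 (AT2G34600, listed as TIFY 5B; chromosome 2, 14573030 to 14573952), a jasmonate-induced repressor, was higher in stabilised leaves at 44.7 ± 47.2 against 0.613 ± 0.259 RPKM (n = 3 each, log2 6.43, SE 1.01, adjusted p = 0.0185). LOX4 (AT1G72520; chromosome 1, 27308513 to 27312756), of jasmonate synthesis, was 12.1-fold higher at 84.7 ± 41.8 against 8.09 ± 2.08 RPKM (SE of log2 0.53, adjusted p = 0.016), with 22.9 ± 12.7 in the wild type. SOT17 (AT1G18590; chromosome 1, 6398531 to 6400029) was higher at 68.4 ± 4.98 against 33.8 ± 4.86 RPKM (log2 1.21, SE 0.14, adjusted p = 0.0132). EdgeR's quasi-likelihood test called 1351 genes, 945 higher and 406 lower in stabilised leaves, 582 and 117 of them at least 2-fold, and 5935 had an unadjusted p under 0.05. Groups did not overlap for 6122 genes, or 31.5%, where chance gives 10%.

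**Figure D3:**
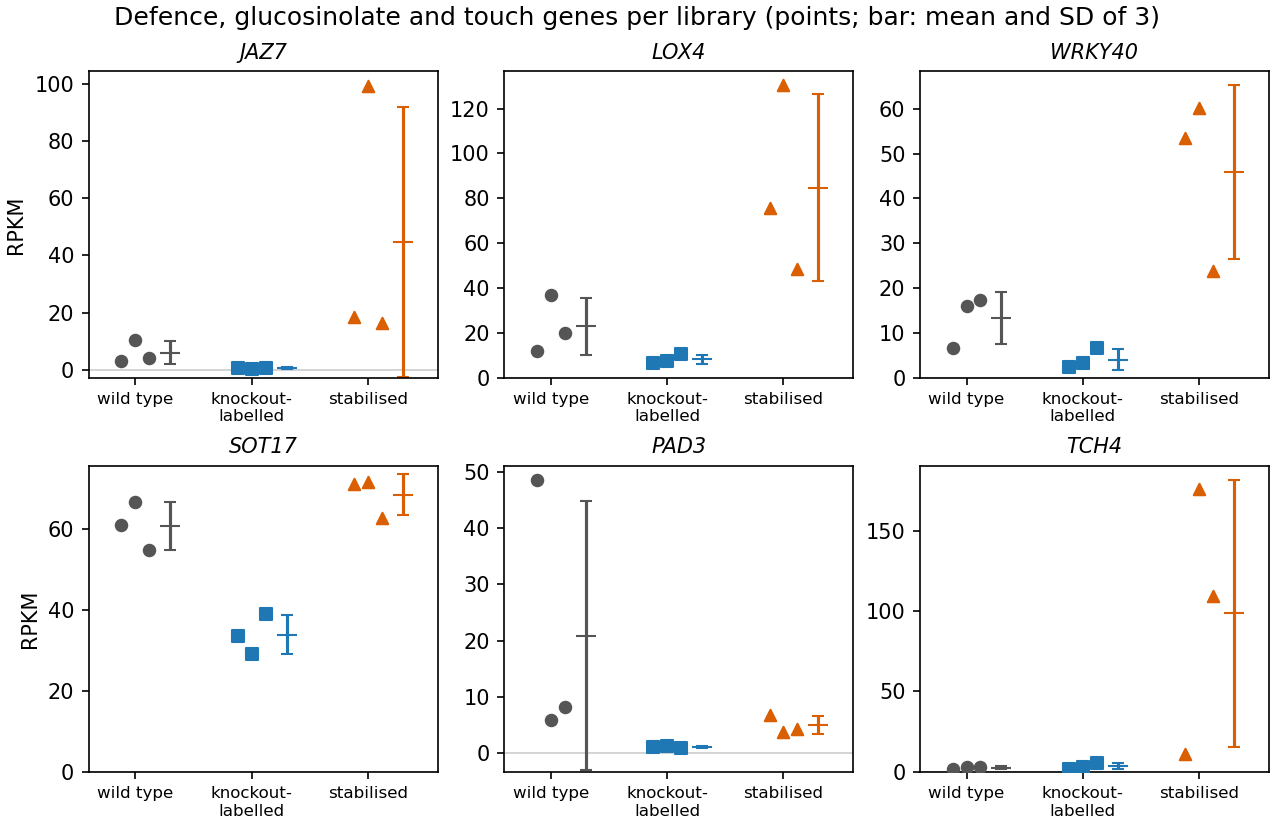
RPKM of 6 defence, glucosinolate and touch genes in each library (points), with the mean and SD of 3 libraries per group (bars). SOT17 averages 33.8 RPKM in the knockout-labelled line against 60.7 and 68.4 in the wild type and the stabilised line, and JAZ7 and TCH4 spread widely among stabilised libraries.

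Jasmonate and ethylene genes were higher for 12 of 26 members, 16 when adjusted over the list alone, with 25 above 0 (median 2.16, camera adjusted p = 3.34e-08, and adjusted p = 0.478 with an estimated correlation). JAZ1 (log2 3.14, adjusted p = 0.0221) and JAZ8 (4.95, adjusted p = 0.0235) were among them. This count was 0 without knockout-labelled 1 or 2, 4 without knockout-labelled 3, 5 without stabilised 2, 8 without wild type 3 and 16 of 26 without stabilised 1, while the median stayed at 1.53 or above. Of 20 glucosinolate genes 10 rose, 13 when adjusted over the list alone, and all 20 were above 0 (median 1.00, camera adjusted p = 3.34e-08, and adjusted p = 0.285 with an estimated correlation), with CYP79F1 at 1.25 (adjusted p = 0.0135). The list mean was -0.02, 0.73 and 0.47 in stabilised 1, 2 and 3, against -0.61, -0.82 and -0.15 in knockout-labelled 1, 2 and 3. In pattern-triggered immunity 9 of 21 rose, 14 when adjusted over the list alone (median 1.21, camera adjusted p = 8.94e-08, and adjusted p = 0.285 with an estimated correlation). WRKY40 rose from 4.01 ± 2.28 to 45.9 ± 19.4 RPKM (log2 3.70, adjusted p = 0.0181), CYP81F2, of indole glucosinolate modification, by 3.82 (adjusted p = 0.0212) and MPK3 by 0.95 (adjusted p = 0.0201). Of 26 salicylic acid genes 3 rose, 4 when adjusted over the list alone (median 0.52, and 0.26 without stabilised 1, camera adjusted p = 0.00106, and adjusted p = 0.638 with an estimated correlation). They were GRX480 (3.23, adjusted p = 0.0183), PR5 (1.94, adjusted p = 0.0446) and SAG101 (0.98, adjusted p = 0.0134).

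The largest rise among genes with a mean of at least 1 RPKM was that of AT1G66860, a glutamine amidotransferase-like gene (256-fold, adjusted p = 0.029), at 5.99, 167 and 17.9 RPKM in stabilised 1, 2 and 3. JAZ13 (7.00, adjusted p = 0.0439), EXL1_1 (6.46, adjusted p = 0.0322), AT5G12340 (5.94, adjusted p = 0.0135) and MAPKKK21 (5.60, adjusted p = 0.0134) were higher too. The flavonol regulator MYB11 (-2.78, adjusted p = 0.0383), AT3G09450 (-2.36, adjusted p = 0.0316), AT1G01520 (-2.22, adjusted p = 0.0485), AT1G59950 (-2.12, adjusted p = 0.0476), PELPK1 (-2.00, adjusted p = 0.0489) and HHT1 (-1.99, adjusted p = 0.0371) were lower.

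Of 14 clock genes 5 were higher and 4 lower, and 6 and 5 when adjusted over the list alone (median 0.32, camera adjusted p = 0.315, and adjusted p = 0.650 with an estimated correlation). Fry gave this list adjusted p = 0.0453 for 1 direction and adjusted p = 7.63e-05 for mixed directions. PRR5 rose by 2.18 (adjusted p = 0.00252) and LHY fell by 1.72 (adjusted p = 0.0153), and LUX rose by 2.07 (adjusted p = 0.0238) with 65.7% of its reads unique. PRR3, TOC1 and BOA were the other genes that rose, and CCA1, RVE8 and PRR9 the others that fell. Of 18 abscisic acid, drought and cold genes 6 rose, and 10 were higher and 1 lower when adjusted over the list alone (median 0.88, camera adjusted p = 0.00331, and adjusted p = 0.285 with an estimated correlation). Among them were COR15B (2.18, adjusted p = 0.0185), RD29B (2.61, adjusted p = 0.0238) and CBF3 (0.90, adjusted p = 0.028). EdgeR called 0 of 9 heat shock genes and 5 lower when adjusted over the list alone, with 6 lower unadjusted and 3 by DESeq2 (median -1.27, camera adjusted p = 0.0081, and adjusted p = 0.611 with an estimated correlation). HSP90.1 stood at 7.01 ± 3.91 against 19.4 ± 5.46 RPKM (adjusted p = 0.0926). Flavonoid synthesis had 0 calls on either adjustment with all 15 members below 0, 2 lower unadjusted and 0 by DESeq2 (median -1.43, camera adjusted p = 0.00476, and adjusted p = 0.650 with an estimated correlation). CHI gave -0.90 (adjusted p = 0.135). The list mean in stabilised 1 (1.19) lay among those of knockout-labelled 1, 2 and 3 (0.99, 2.27 and -0.72). The median was -4.62, -0.87 and -0.90 without stabilised 1, 2 or 3 and -0.39 without knockout-labelled 2. Photosynthesis had 0 calls on either adjustment with 26 of 27 above 0, 7 higher unadjusted and 1 by DESeq2 (median 0.64, camera adjusted p = 0.000501, and adjusted p = 0.675 with an estimated correlation). RBCS2B gave 1.23 (adjusted p = 0.123). The difference came from stabilised 2 and 3, as the list mean of stabilised 1 (-0.50) was level with knockout-labelled 1 and 2 (-0.53 and -0.45). Trichome and stomatal markers were lower for 3 of 5 members and all 5 when adjusted over the list alone (median -0.88, camera adjusted p = 0.000971, and adjusted p = 0.285 with an estimated correlation). They were GL2 (-1.36, adjusted p = 0.0201), MYB60 (-0.75, adjusted p = 0.0286) and FAMA (-0.62, adjusted p = 0.0431).

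Of 22 Aux/IAA genes IAA3 rose (1.33, adjusted p = 0.0303) and IAA13 fell (-0.57, adjusted p = 0.0453), with 3 and 2 when adjusted over the list alone (median 0.24, camera adjusted p = 0.448, and adjusted p = 0.862 with an estimated correlation). Of 21 auxin-induced, transport and perception genes 0 rose and 2 fell, also when adjusted over the list alone, with AFB3 among them (-0.37, adjusted p = 0.0434). The median of 0.14 turned negative with library totals alone (camera adjusted p = 0.804, and adjusted p = 0.914 with an estimated correlation). In the senescence list 4 of 22 rose and NAP fell (-1.25, adjusted p = 0.0286), 5 and 2 when adjusted over the list alone. SEN1 rose by 3.24 (adjusted p = 0.0317), SAG14 by 3.16 (adjusted p = 0.046), WRKY53 by 2.88 (adjusted p = 0.0484) and SAG21 by 1.35 (adjusted p = 0.0279). The median of that list was -0.16 and its mean 0.11 (camera adjusted p = 0.974, and adjusted p = 0.988 with an estimated correlation). Of 19 phase change and flowering genes MAF5 (3.09, adjusted p = 0.00999) and SPL5 (1.58, adjusted p = 0.0464, 35.7% unique) rose and TSF (-1.23, adjusted p = 0.0426) and SPL10 (-0.99, adjusted p = 0.0476) fell. It was 3 and 3 when adjusted over the list alone (median -0.22, camera adjusted p = 0.315, and adjusted p = 0.611 with an estimated correlation). TCH4 was the 1 of 12 cell expansion genes that rose (5.11, adjusted p = 0.0307), also when adjusted over the list alone (median 0.82, camera adjusted p = 0.340, and adjusted p = 0.862 with an estimated correlation).

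On either adjustment edgeR called 0 members of the last 5 lists. RNA silencing had a median of -0.21 over 18 genes, 1 higher and 6 lower unadjusted and 1 lower by DESeq2 (camera adjusted p = 0.130, and adjusted p = 0.650 with an estimated correlation), with RDR6 at -0.18 (adjusted p = 0.1). Dividing cells had a median of 0.25 over 11 genes, 0 unadjusted and 0 by DESeq2 (camera adjusted p = 0.663, and adjusted p = 0.866 with an estimated correlation), with CYCD3;1 at 0.83 (adjusted p = 0.332). Phloem markers had a median of 0.05 over 10 genes, which turned negative with library totals alone and against which camera pointed down, 1 lower unadjusted and 0 by DESeq2 (adjusted p = 0.804, and adjusted p = 0.866 with an estimated correlation), with APL at -0.22 (adjusted p = 0.163). Xylem markers had a median of 0.91 over 6 genes, 0 unadjusted and 0 by DESeq2 (camera adjusted p = 0.377, and adjusted p = 0.862 with an estimated correlation), with XCP2 at 1.60 (adjusted p = 0.187). Flower, meristem and seed markers had a median of -1.21 over 4 genes, 0 unadjusted and 0 by DESeq2 (camera adjusted p = 0.340, and adjusted p = 0.768 with an estimated correlation), with PI at -1.98 (adjusted p = 0.173) through knockout-labelled 3.

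**Figure D4:**
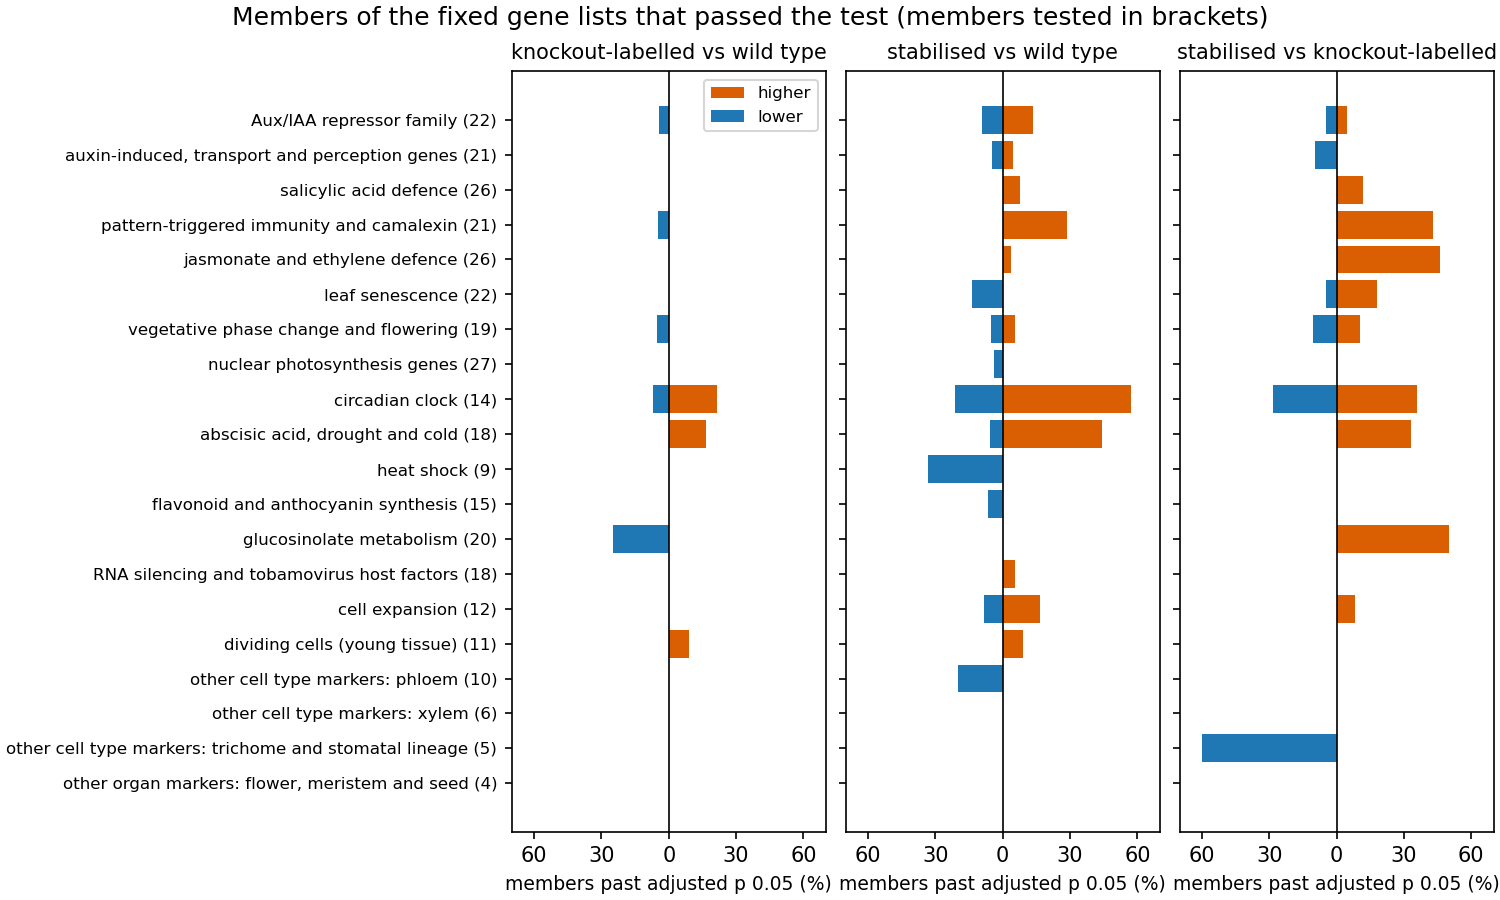
Percent of the tested members of each of 20 gene lists that edgeR called higher (right) or lower (left) at an adjusted p of 0.05 over all genes, in the 3 comparisons. Of the clock list, 8 of 14 members were higher and 3 lower in stabilised against wild-type leaves, and 10 of 20 glucosinolate genes were higher in stabilised than in knockout-labelled leaves.

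The count of 1351 genes was 3 and 8 without knockout-labelled 1 or 2, 869 without knockout-labelled 3, 5241, 158 and 489 without stabilised 1, 2 or 3 and 758 and 646 without wild type 2 or 3. Of the 50 calls picked by the naming rule 1, that of PRR5, held in all 9 such fits. The 945 higher and 406 lower genes became 635 and 876 with library totals alone, which moved the median of all genes by -0.19, 677 and 1445 with limma on RPKM and 787 and 902 after quantile normalization, while DESeq2 called 3641. Medians of further lists, not called by camera, moved by over 1.5 times without 1 library. Their ranges, with the library left out at each end, were: Aux/IAA genes 0.08 (stabilised 3) to 0.41 (stabilised 1), auxin-induced, transport and perception genes -0.07 (stabilised 3) to 0.26 (stabilised 1) and senescence -0.37 (stabilised 1) to 0.08 (stabilised 3). Other ranges were: cell expansion 0.48 (stabilised 3) to 1.57 (knockout-labelled 3), dividing cells -0.13 (knockout-labelled 1) to 0.77 (knockout-labelled 3) and phloem -0.04 (stabilised 3) to 0.13 (stabilised 1). Other ranges were: xylem 0.52 (knockout-labelled 1) to 1.88 (knockout-labelled 3) and flower, meristem and seed -2.43 (knockout-labelled 1) to 0.24 (knockout-labelled 3). Across the 3 comparisons camera with a preset correlation called 6, 6 and 9 lists, and with an estimated correlation 0, 0 and 0, where 1, 1 and 2 had an unadjusted p under 0.05 and fry called 4, 3 and 7.

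The responses of both lines were compared with each other. Of the genes called against the wild type, 145 were higher in both lines and 53 lower in both, against 9.15 and 5.37 for independent lists of these sizes, which leave the shared controls out of account. PRR5, CBF3, ADO3, COR15B and ELF3 were higher in both, and LHY and IAA17 lower in both. In edgeR's fit of all 9 libraries UGT74E1 was the only gene called in opposite directions. It changed by -2.94 in the knockout-labelled (adjusted p = 0.0164) and by 1.61 in the stabilised line (adjusted p = 0.0163). With the replicate number as a block edgeR called 5 genes in opposite directions, and DESeq2 called 52. Across 19409 genes, which are not independent replicates, the log2 fold changes correlated at 0.239, below the 0.494 (0.458 to 0.532) that shared controls alone gave in 20 simulations of unchanged groups, and 58.2% had the same sign against 66.7% simulated. Their covariance was 0.0957 against a simulated 0.0688 (0.0613 to 0.0763), a difference of 0.0269. The simulation drew each gene independently, so its ranges leave out deviations that many genes of 1 library share. Whether these values lie outside what the real shared controls give is therefore not known. The 3 wild-type libraries cannot be divided into sets of 2 or more, so how much of the excess of shared calls comes from the shared controls is not known. The 198 shared calls became 70, 69 and 23 without wild type 1, 2 or 3, 131 and 68 without stabilised 2 or 3, 10, 10 and 82 without knockout-labelled 1, 2 or 3, and 832 with DESeq2.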

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

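All tests in this part were chosen after the result they bear on was seen, except that of the jasmonate list without each single library, which was set out before.

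Intron reads, which no comparison above used, also differed between the groups. Over 11289 genes with enough intron reads, edgeR called 70 genes in knockout-labelled against wild-type leaves, 550 in stabilised against wild type and 598 in stabilised against knockout-labelled. Of those also tested on exon reads, 67 of 67, 520 of 531 and 559 of 582 had the same sign there, and 36, 328 and 271 were called there. Intron reads of PRR5 went from 2 in the 3 wild-type libraries together to 87 in the 3 stabilised libraries, and those of RBG7, a clock-controlled RNA-binding protein, from 1399 to 34597. Intron reads made up 5.79% ± 0.357 (SD, n = 3) of the reads at IAA26 in knockout-labelled leaves, 4.25% ± 0.532 in the wild type and 3.24% ± 0.504 in the stabilised line.

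Mean levels of 10 of 14 clock genes stood in the order wild type, knockout-labelled, stabilised, 4 falling along it, LHY among them, and 6 rising, PRR5 and PRR3 among them. PRR7, LUX, BOA and PRR9 did not stand in that order. Both lines share the wild-type libraries, and shared controls alone gave opposite signs against them for 33.3% of all genes in simulation. Of 14 clock genes 3 had opposite signs (binomial test for fewer, p = 0.262). That test takes the genes as independent, which clock genes are not, and rests on only 14 of them. The count of genes alone therefore does not settle whether the lines agree. Opposite effects of removing and of stabilising IAA26 on the clock would not by themselves give this order. The order already places both lines on the same side of the wild type, so the mean of the same genes is no separate test. It cannot tell whether another shift between the groups covers such effects. The mean log2 CPM of the 13 clock genes with a known phase, dawn genes with their sign turned, was 0.734 (SE 0.0805) above the wild type in knockout-labelled and 1.93 (SE 0.144) above it in stabilised leaves, without overlap of libraries, where both SE include the spread of the wild type. Of single genes, LUX, BOA and PRR9 had opposite signs in the 2 lines against the wild type, and for them opposite effects stay open as well. A candidate explanation is that the groups were harvested at different times of day, since all 11 clock genes called in stabilised against wild-type leaves, 3 dawn genes lower and 8 later genes higher, went as a later harvest predicts. Harvest times are not given in the sources used here, so this technical explanation stays open beside an effect of the genotype. List means of the abscisic acid, drought and cold genes stood in the same order of groups. They were -0.86 to -0.72 in wild-type, -0.09 to 0.16 in knockout-labelled and 0.63 to 1.14 in stabilised libraries. Whether harvest time bears on that list was not tested, and it stays open there too.

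Jasmonate genes were lower in knockout-labelled than in stabilised leaves by a median log2 difference of 2.16, with 12 of 26 called. Camera did not call the list with an estimated correlation (adjusted p = 0.478). A single library as the sole cause of that median is argued against, since it stayed at 1.53 or above in each of the 9 fits without 1 library, although the number of called members fell from 12 to 0 without knockout-labelled 1 or 2, to 4 without knockout-labelled 3, to 5 without stabilised 2 and to 8 without wild type 3. Touch or wounding of leaves before freezing may contribute: 16 genes of fast touch and wound responses, outside the fixed lists, had a median of 2.36 in the same comparison, and 8 of them were called higher (camera p = 0.0591 with an estimated correlation). The touch and jasmonate list means did not go together in every library. Stabilised 1 had the highest touch mean (1.85) but a jasmonate mean of -0.02, and wild type 1 stood at -1.22 and 0.89. In stabilised 2 they were 1.59 and 1.73, and in stabilised 3 0.68 and 0.71. Knockout-labelled libraries were low in both, at -1.28 to -0.88 and -1.81 to -0.88. Handling and genotype cannot be separated here, and both stay open.

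IAA26 transcript at 82.5% of the wild-type level by RPKM means in knockout-labelled leaves was weighed as well. Reads of related family members counted at IAA26 are argued against, since 100% of its exon reads were unique. An exchange of the labels of both altered lines stays open, because the stabilised-labelled libraries held 58.4% of the wild-type level, which is neither the loss nor the excess that would decide it. A lesion that spares the transcript is a biological explanation that was not tested, since no reads were analysed here.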

How the results depend on the processing

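The alternatives with unique exon reads, total gene reads and the libraries numbered 2 were chosen after seeing the data. Of the genes called in each comparison and tested under an alternative, 0, 0 and at most 1 had the opposite sign in any of 28 alternative fits or thresholds. That 1 was in stabilised against knockout-labelled leaves with unique exon reads and was not called there. Thresholds of 0.01 and 0.1 and the test against a fold of 1.5 keep the counts and groups of the main fit, so they could not turn a sign. Groups did not overlap for 322 of the 322, 1717 of the 1721 and 1349 of the 1351 called genes. Few signs could therefore turn under the other alternatives, and their agreement is no separate support. Scaling moved the balance of higher and lower calls as given above. RLE factors, either filter, organelle genes left out, quantile-normalized RPKM and both other read counts moved no total of called genes by over 1.5 times, though quantile normalization took the lower calls of the last comparison from 406 to 902. DESeq2, which made 66, 74 and 45 calls among unchanged simulated genes against 5, 7 and 7 by edgeR, called 1778, 3418 and 3641 genes (knockout-labelled against wild type, stabilised against wild type, stabilised against knockout-labelled) with 832 shared, and put IAA26 in the knockout-labelled line past the threshold at -0.40. The simulated genes were drawn with edgeR's estimates of spread, so they do not give the false share of these real calls. Limma on RPKM gave 2122, 2094 and 2125 genes in the last comparison with pseudocounts of 0.5, 0.1 and 1. Fits of only the groups compared gave 615 and 703 genes for stabilised leaves against wild type and knockout-labelled. An adjusted p of 0.01 left 11, 398 and 19 genes and one of 0.1 gave 937, 3150 and 3515; a test against a fold of 1.5 left 13, 237 and 69. IAA26 in stabilised leaves, at -0.70, missed the threshold of 0.01 in edgeR's main quasi-likelihood test (adjusted p = 0.0112). With the stricter filter the same test gave adjusted p = 0.00912. The test against a fold of 1.5, which asks for more than a difference from 0, did not call it. Over all alternatives, this test included, its adjusted p was 6e-06 to 0.684. Without each library in turn, the counts ranged from 10 to 546, 584 to 3786 and 3 to 5241 genes, the shared calls from 10 to 287, and the called lists from 6 to 9, 5 to 6 and 8 to 10. IAA26 ranged from -0.46 to -0.28, -0.76 to -0.64 and -0.42 to -0.24. With an estimated correlation camera called 0, 0 and 0 lists where 1, 1 and 2 had an unadjusted p under 0.05; fry called 4, 3 and 7, and 8, 11 and 12 for mixed directions. Without 1 of the libraries the median of 8, 2 and 5 lists turned sign, 0, 0 and 0 of them lists that camera called with a preset correlation. A term for the libraries numbered 2 left 169 genes in the first comparison. With only the 6 libraries numbered 1 and 3, edgeR called 0, 19 and 0 genes, with 1933, 2902 and 2020 at an unadjusted p under 0.05 and 638, 1527 and 802 by DESeq2. IAA26 in stabilised leaves then stood at -0.70 without a call; fewer libraries are part of that construction. Replicate numbers were not taken as pairs, since deviations from the group means correlated from -0.44 to 0.52 between same-numbered libraries, and 4 of 9 correlated best with their own number. A shared batch by number is not excluded: stabilised and knockout-labelled 1 and 3 correlated at 0.49 and 0.52, and the libraries numbered 2 had an intron share of 3.79% to 4.03% in all groups against 4.61% to 4.99%. With the replicate number as a block, 134 genes were called in the first comparison and 91 calls were shared, the other counts staying within 1.5 times. Where no construction is named, the cause was not tested. Of 118 calls picked by the naming rule, 116 were kept by DESeq2, 109 with library totals alone and 90 with the block, and 24 in all 9 fits without 1 library. Fits of only the 2 groups compared kept 71, and 19 of 45 in the second comparison. The test against a fold of 1.5 kept 23, the threshold of 0.01 kept 21 and the 6 libraries numbered 1 and 3 kept 4. The block kept 12 of 23 such calls in the first comparison, 37 of 45 in the second and 41 of 50 in the third. Other splits of the 6 libraries of a comparison are 10 in number, the real one included, too few for a share under 0.05. Of the 10, 1, the real one, gave as many genes in each comparison, with 322, 1721 and 1351 genes for the real split and 0, 0 and 450 at most for another (at an unadjusted p under 0.05, 1267, 3295 and 5917). The 450 came from setting stabilised 1 with knockout-labelled 1 and 2, which points to structure among the samples. With these libraries many 2-fold changes are missed, as the simulated recovery shows. Depth was not varied there, so its part in this is not known.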

Other observations

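The 2 lists in this part and the tests on them were chosen after the results were seen. Of 15 genes of iron supply edgeR called 6 lower in knockout-labelled leaves and left 9 uncalled, with 3 above 0 and a median log2 fold change of -1.33. DESeq2 called 11 lower and 2 higher. The 6 edgeR calls became 0 without wild type 3 or knockout-labelled 1 or 2, and 1 without knockout-labelled 3 or stabilised 3. They became 2 without wild type 1, 3 without wild type 2 or stabilised 2, and 7 without stabilised 1. In each of these fits 11 or 12 were lower at an unadjusted p under 0.05. Besides the transcription factors BHLH100 and bHLH38, the peptide genes IMA1 (log2 -2.49, adjusted p = 0.0302) and IMA2 (-1.83, adjusted p = 0.0184), the reductase FRO3 (-0.64, adjusted p = 0.0412) and the transporter OPT3 (-0.95, adjusted p = 0.0423) fell by edgeR's quasi-likelihood test. The iron stores FER1 and FER4, which iron induces, gave 1.68 (adjusted p = 0.0871) and 1.35 (adjusted p = 0.0506) without a call by edgeR. Camera gave p = 2.3e-07 with a preset correlation and p = 0.0561 with an estimated one, so the hypothesis of a lower iron response as a group, found from members already seen, stays open. In stabilised leaves edgeR called 3 of the 15 lower against the wild type (median -0.53), and DESeq2 called 4. Against knockout-labelled leaves edgeR called 3 higher and 1 lower (median 0.51), and DESeq2 called 5 and 2.

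The 16 touch and wound genes stood at a median of 1.61 in stabilised against wild-type leaves, all 16 above 0, and at -0.85 in knockout-labelled leaves. In both comparisons edgeR called 0 of 16, with 12 higher in stabilised and 5 lower in knockout-labelled leaves at an unadjusted p under 0.05, and 11 and 3 by DESeq2. Camera gave p = 0.114 and 0.333 with an estimated correlation. The touch list mean of wild type 1 (-1.22) lay among those of the knockout-labelled libraries (-1.28 to -0.88), while wild type 2 and 3 stood at -0.02 and 0.23. PRR9, 1 of the 4 clock genes outside the order of the other 10, was highest in the knockout-labelled line: it stood at 31.6 ± 12.1 RPKM in the wild type, 60.8 ± 12.9 in the knockout-labelled and 22.7 ± 8.11 in the stabilised line, and differed between both lines (log2 -1.24, adjusted p = 0.0496).

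Genes near IAA26 were examined for a segment from another accession, which a cross could have left in the knockout-labelled line. Within 2 Mb of IAA26, 11 of 841 tested genes were called in that line, or 1.31%, against 1.67% elsewhere (ratio 0.781, Fisher's exact test, p = 0.491), which argues against such a segment with many altered genes.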
